A study of Mus musculus with 5 samples.

How the data were processed

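Liver RNA was measured on 5 Agilent 2-colour mouse whole-genome arrays. On 4 arrays, RNA of 1 Fra-1hep mouse each was labelled with Cy5 and hybridised against a Cy3-labelled pool of 5 control mice. On 1 further array the dyes were swapped, with the control pool in Cy5 and a pool of Fra-1hep RNA in Cy3; which mice entered that pool is not given in the sources used here. If they were the same 4 mice, that array adds no animals, and agreement on all 5 arrays is not that of 5 independent samples. Per the labels, the mice were 26 to 28 weeks old and had eaten a diet with 45% of energy from fat since 4 weeks of age. Also per the labels' protocols, RNA had an integrity score above 7.8 and 100 ng was labelled.

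The scanner files hold spot intensities that the authors extracted with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.3.1 per the file headers. They give raw median signals and local backgrounds per spot, processed signals that the software had background-subtracted and dye-normalized, a log10 ratio of Cy5 over Cy3, and 0 or 1 flags for background, saturation and spot uniformity, per the file headers. The deposited series table holds log2 ratios. Set against the scanner ratios of 23104 probes above background in both channels on all 5 arrays, its columns had slopes of 1.00 for the 4 mice and -1.00 for the swapped array. Its scale is therefore log2 and its sign is Fra-1hep over control on every array. The columns were not centred, with medians of 0.13, 0.08, 0.04 and 0.13 for mice 1 to 4 and -0.04 for the swapped array; any further step behind them is not given in the sources used here.

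Raw median signals were corrected with normexp (offset 50) on the local backgrounds and normalized by loess within each array, with control spots and non-uniformity outliers at weight 0. Each array had 62976 spots; 189 outlier spots over the 5 arrays were left out, and 0 spots were saturated. The design fixed before the data were examined assumed mean signals and a gene name column; the files used here hold median signals and accessions, so both were used in their place. Of 55681 distinct probes, 26056 were named through their accession, without version, in a RefSeq gene table of the GRCm38.p6 assembly, which gave 19752 genes; 29625 probes kept their accession as the file gives it. The table served for names and gene neighbours alone. Spots of 1 probe were averaged. A probe was kept where it was well above background in either channel on at least 3 arrays (28115 probes), and the brightest kept probe stood for its gene, which left 21494 features: 13524 named genes and 7970 accessions without a name. Of 3281 named genes with over 1 kept probe, 16 had probes past the threshold in both directions.

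Log ratios were fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) with a genotype coefficient, coded 1 for the mice and -1 for the swapped array, and a dye intercept per gene. Fold changes below are this genotype coefficient, log2 of Fra-1hep over control, ± its moderated standard error, over 4 mice and the swapped pool. The swapped array has as much weight in it as the 4 mice together. The spread comes from the 4 mice (3 residual degrees of freedom, 4.02 prior degrees of freedom), since the dye term leaves the swapped array no residual of its own. For the same reason, each dye effect given below may also be a deviation of the swapped array or of its Fra-1hep pool. The control pool counted as 1 control sample, so each test leaves out the spread among control mice. P-values were adjusted by Benjamini-Hochberg over the 21494 features, with a threshold of 0.05. The number of arrays limits the precision: the median standard error of named genes was 0.067 on the log2 scale. Where the Fra-1hep or the control channel was not well above background on any array, the change is given as a bound. It sets the measured group's mean against, per array, the higher of the probe's own level and the lowest level among probes well above background. These levels were taken per channel after loess and Aquantile, and they stay open to dye bias because the swap is not balanced. In 13 lists with such members, placing them at the bound moved a list's median by at most 0.06.

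Before the data were examined, 41 gene lists with 1097 genes were fixed, of which 948 genes were tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 41 lists, with camera at an estimated correlation and fry beside it. The genes to be named were also fixed in advance: Fosl1, all AP-1 subunits past the threshold, the 12 largest rises and 12 largest falls among genes past the threshold with 1 sign on all 5 arrays (leaving out names that are only clone or predicted-gene numbers), and for each list the up to 4 members with the smallest p. Genes named outside this rule are said to be chosen after their values were seen. Not every gene that the rule takes is reported here. Alternatives covered the dye term, background correction and offset, normalization, the deposited values, filters on dim probes, the probe rule, moderation, array weights, the slide, a minimum fold change and each mouse left out. Mouse 1 lay on slide 1 and scan 1 and the other 4 arrays on slide 2 and scan 2, so a slide block equals leaving out mouse 1.

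The fit was tested on simulated data with 21494 features and 200 changed ones, at the estimated spread and dye effects. It recovered 2% of changes of 0.3 on the log2 scale, 54% of 0.5, 96% of 1 and 100% of 2, with 7 false calls (5.26% of all calls). In a second simulation, a list shifted by 0.5 was called and 0 other lists were. Both simulations drew genes independently and gave the control pool no deviation of its own. They therefore could not show errors that come from correlated genes or from the pool. The 200 changed features are also far fewer than the 5717 called in the real data, so the share of small changes recovered does not carry over.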

Results

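Fra-1, encoded by Fosl1, is a FOS-family subunit of the AP-1 transcription factor. Livers of 4 Fra-1hep mice, which overexpress it in hepatocytes, were compared with livers of control mice on the same high-fat diet. Each Fra-1hep mouse had 1 array against a pool of 5 control mice, and 1 more array compared both pools with the dyes swapped. The share of spots well above background ran from 47.2% to 54.7% in Cy5 and from 47.7% to 61.5% in Cy3. Across genes, which are not independent replicates, log ratios of the mice correlated with r of 0.74 to 0.84; sharing 1 control pool and 1 dye orientation raises these values even without a genotype effect. Those of the swapped pool, with the sign turned, correlated with the mice at 0.59 to 0.61. The comparison asks which liver transcripts differ when hepatocytes carry extra Fra-1 during high-fat feeding.

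Fosl1 itself had 1 probe, which lay near background. The Fra-1hep channel was not well above background on any of the 5 arrays and the control channel was on 1. Log2 ratios of Fra-1hep over control were -0.37, -0.23, 0.11 and 0.12 in mice 1 to 4 and -0.09 in the swapped pool. No fold was drawn from this probe. Whether it covers the transcript that the mice overexpress is not given in the sources used here, so it did not check the labels.

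The largest rise was in Asns, asparagine synthetase, at 58.3-fold (log2 5.87 ± 0.24, adjusted p = 2.61e-05), with ratios from 5.01 to 6.35 in the 4 mice and 6.07 in the swapped pool. Mep1a, a subunit of the protease meprin, rose 16.9-fold, and the trefoil factor gene Tff3 rose 14.9-fold. Cyp4a14, a fatty acid hydroxylase, fell by 5.80 on the log2 scale (SE 0.34, 55.8-fold, adjusted p = 9.54e-05). Cidea, a lipid droplet protein, fell by 5.48 (SE 0.06, 44.7-fold, adjusted p = 9.93e-08). Among the other large rises were Lrtm2 (3.84), Inava (3.75), Meltf (3.58), the annexin Anxa13 (3.51), the elastase Cela1 (3.34), Enho, which encodes the secreted peptide adropin (3.34), the trypsin inhibitor Spink1 (3.02), Lysmd2 (2.94) and the membrane protease St14 (2.89). Other large falls were those of the lipid droplet protein Plin4 (-3.80), Hsd17b6 (-3.69), the major urinary protein genes Mup19 (-3.24, with a dye effect of 0.64, and -2.59 without the swapped array) and Mup2 (-3.05), Kyat3 (-3.22, and -1.77 at its other probe), Serpina4-ps1 (-3.21), the serum amyloid gene Saa2 (-3.10), Adgrv1 (-3.02) and Rad51b (-3.02). Cfd, which encodes adipsin, was not well above background in the Fra-1hep channel of any array and was at least 10.3-fold lower (adjusted p = 5e-05).

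**Figure D1:**
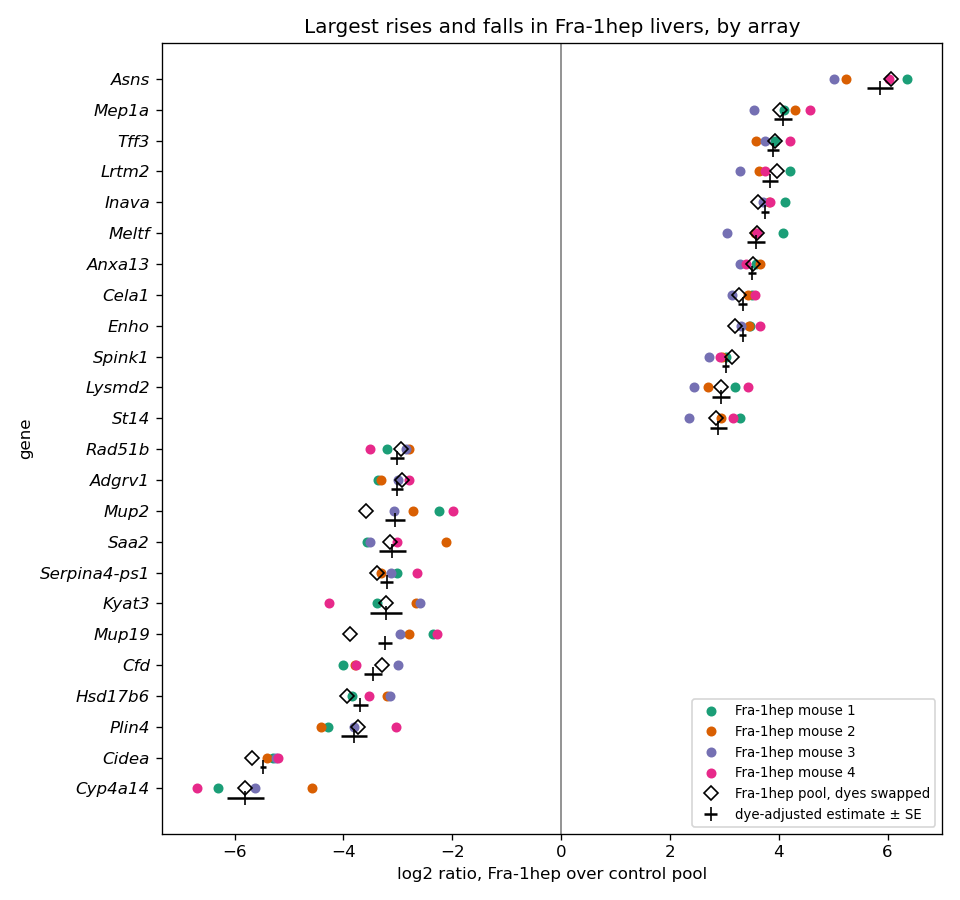
Log2 ratios of Fra-1hep over the control pool (horizontal axis) for the 12 largest rises and 12 largest falls (vertical axis); filled circles are the 4 mice, open diamonds the pool with swapped dyes, and black bars the dye-adjusted estimate ± SE. Asns lies above 5 on every array and Cidea below -5, and the values of Cfd rest on a Fra-1hep channel not well above background.

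In total, 4129 of 13524 named genes passed the threshold, of which 1625 rose and 2504 fell. Changes of at least 2-fold made up 305 of them, with 122 rises and 183 falls, and 3552 went the same way on all 5 arrays. With unnamed accessions included, 5717 of 21494 features passed, 2402 higher and 3315 lower. Because controls were pooled, standard errors were also enlarged for 5 control mice that vary as the Fra-1hep mice do, a setting chosen after seeing the data, and 2846 features then passed. Against a minimum change of 1.2-fold, 1051 passed. Members of the Mup, Cyp4a, Cyp3a, Cyp2c, Saa, Gstm, Gstp and globin families resemble each other. A probe may therefore read several of them, and their single values are uncertain.

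Camera called 19 of the 41 lists, 3 higher and 16 lower. With an estimated correlation 0 lists were called, and the lowest adjusted p was 0.405. Fry called 17 lists in 1 direction and all 41 for change in either direction. It asks whether members change at all, not whether they change more than other genes, so calling all 41 sets no list apart. Of camera's lists, fry did not call neutrophil (fry adjusted p = 0.169), cholesterol (0.0987), cell cycle (0.0965), fatty acid oxidation (0.053) or endothelial genes (0.0506). It called hepatocyte identity (0.0166), adipocyte (0.00228) and skeletal muscle genes (0.0195), which camera did not. At an unadjusted p under 0.05, 2 lists passed by camera with an estimated correlation.

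Genes of lipid droplets and targets of PPAR gamma, the nuclear receptor that drives fat storage, were mostly lower. Of 29 tested members, 16 fell, 4 rose and 9 did not pass (17 and 4 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 4.49e-05; adjusted p = 0.405 with an estimated correlation). Pparg itself fell by 1.82 (SE 0.05, adjusted p = 8.41e-06), beside Cidea, Plin4 and Cfd. Cd36, chosen after its value was seen, lay at 0.02 and did not pass. The 4 that rose were Vldlr (0.99), Mogat1 (0.92), Apoa4 (0.89) and Mogat2 (1.09), also chosen after their values were seen.

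Fatty acid oxidation and ketogenesis genes were also lower: 19 of 41 fell, 2 rose and 20 did not pass (23 and 3 adjusted over the list alone; camera adjusted p = 0.00011; adjusted p = 0.626 with an estimated correlation). With the control pool's spread added, 9 fell and 2 rose, and without the swapped array 5 rose. Beside Cyp4a14, the peroxisome gene Pex11a (-1.50 ± 0.10) and the fatty acid binding protein gene Fabp1 (-1.73 ± 0.12) fell. Fabp1 had a dye effect of 0.79: without the swapped array its value was -0.94, and the swapped pool gave -2.53. Cholesterol synthesis genes moved up, with 12 of 25 higher, 2 lower and 11 not passing (13 and 3 adjusted over the list alone) and a median of 0.36. The adjusted p was 0.000473 by camera and 0.701 with an estimated correlation, and with the pool's spread 8 rose and 0 fell; 1 fell without mouse 4 and 4 without the swapped array. Sqle, squalene epoxidase, rose by 1.85 ± 0.13, Mvk by 0.93 ± 0.06 and Msmo1 by 0.78 ± 0.08 (0.42 without the swapped array). Srebf2, the regulator of this pathway, rose by 0.37 ± 0.05 at its brightest probe, while its second probe gave -0.06 and the mean of both did not pass (adjusted p = 0.116).

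Among bile acid genes, 12 of 25 fell, 3 rose and 10 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.405 with an estimated correlation). The rises numbered 1 with the control pool's spread, 1 without mouse 3 and 6 without the swapped array. The transporter Slco1a4 (-2.07 ± 0.10), Cyp8b1, the sterol hydroxylase of cholic acid synthesis (-1.13 ± 0.09), Hsd3b7 (-0.93 ± 0.10) and the receptor Fgfr4 (-0.79 ± 0.08) fell. Conjugation and glutathione genes went both ways, with 19 of 45 lower, 9 higher and 17 not passing (24 and 9 adjusted over the list alone). Camera placed them lower (adjusted p = 0.0106; adjusted p = 0.405 with an estimated correlation), and that call ended without genes shared with other lists (adjusted p = 0.163, a setting chosen after seeing the data) and under median centring (adjusted p = 0.0703). Sult5a1 (-0.95 ± 0.07) and the oestrogen sulfotransferase Sult1e1 (-0.72 ± 0.06, its Fra-1hep channel well above background on 2 of 5 arrays) fell. The glutathione transferases Gstm7 (0.97 ± 0.05) and Gstm5 (1.16 ± 0.10) rose, while Gstm1 fell (-0.56 ± 0.08, and -0.44 at its other probe).

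Targets of NRF2, the regulator of the antioxidant response, had 11 of 21 members lower, 0 higher and 10 not passing (13 lower adjusted over the list alone; camera adjusted p = 0.000115; adjusted p = 0.405 with an estimated correlation). Without mouse 4, 7 fell, and with the control pool's spread 6 did. Cbr3 (-2.18 ± 0.08), Gsta1 (-1.22 ± 0.18) and Gclc, of glutathione synthesis (-0.79 ± 0.12), fell. Of 25 iron and haem genes, 9 fell, 1 rose and 15 did not pass, the same as adjusted over the list alone; with the pool's spread 3 fell and 0 rose. The list's adjusted p was 0.0463 by camera and 0.567 with an estimated correlation. Its call ended without mouse 1 (adjusted p = 0.0639), with processed signals (0.0542), an offset of 0 (0.0662), the deposited values (0.054), both channels above background on all arrays (0.0551) or array weights (0.0581). It also ended without genes of other lists (0.34, chosen after seeing the data). The ferritin light chain gene Ftl1 fell by 0.90 (SE 0.06), with a dye effect of 0.68: without the swapped array its value was -0.22, and the swapped pool gave -1.58. With that array turned and no dye term it did not pass (adjusted p = 0.0968). Hpx, which encodes the haem carrier hemopexin, fell by 0.96 (SE 0.07; -0.63 without the swapped array).

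The other AP-1 subunits were mostly lower. Of 16 tested, 10 fell, 1 rose and 5 did not pass (14 and 1 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 4.47e-05; adjusted p = 0.405 with an estimated correlation). The falls were those of Jun (-1.39 ± 0.18), Maff (-1.02 ± 0.13), Atf3 (-1.01 ± 0.06), Maf (-0.82, and -0.48 without the swapped array), Batf (-0.75), Fos (-0.64, its Fra-1hep channel well above background on 3 of 5 arrays), Batf2 (-0.52), Jdp2 (-0.33), Jund (-0.30) and Mafg (-0.29), and Mafk rose by 0.46. With the control pool's spread added, the calls of Mafg, Fos, Jund, Mafk and Jdp2 ended (adjusted p from 0.0547 to 0.131), which left 6 falls and 0 rises. Jund did not pass with processed signals or deposited values (adjusted p = 0.0607), nor Mafg with the mean of all probes (adjusted p = 0.0768). Jdp2 also did not pass with the swapped array turned (adjusted p = 0.0911), processed signals or deposited values (0.126) or an offset of 0 (0.087), nor without the swapped array (-0.17, adjusted p = 0.181), mouse 1 (adjusted p = 0.06), mouse 2 (0.0659) or mouse 3 (0.09). Of 28 immediate early genes, 14 fell, 0 rose and 14 did not pass, and the same numbers held adjusted over the list alone (camera adjusted p = 0.000248; adjusted p = 0.587 with an estimated correlation). Egr1 (-1.13 ± 0.13) and Btg2 (-0.83 ± 0.08) fell.

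Markers of macrophages and monocytes were lower in Fra-1hep livers, with 25 of 34 fallen, 1 risen and 8 not passing (27 and 1 adjusted over the list alone) and a median of -0.66 (camera adjusted p = 7.18e-10; adjusted p = 0.405 with an estimated correlation). Gpnmb (-1.88 ± 0.12, its Fra-1hep channel well above background on 1 of 5 arrays), Itgax (-1.28 ± 0.11), the antigen presentation gene Cd74 (-0.99 ± 0.09) and Trem2 (-0.86 ± 0.06) fell. The resident Kupffer cell markers Clec4f (0.07), Vsig4 (0.05) and Timd4 (0.13), chosen after their values were seen, did not pass. Interferon response genes fell in 24 of 31 cases, with 0 rises and 7 not passing, also when adjusted over the list alone (median -0.59, camera adjusted p = 4.42e-10; adjusted p = 0.405 with an estimated correlation). Examples were Igtp (-1.19 ± 0.06), Ifi44 (-1.06 ± 0.09) and Gbp2 (-1.04 ± 0.08). Of 30 cytokine, chemokine and NF-kB genes, 17 fell, 1 rose and 12 did not pass (18 and 1 adjusted over the list alone; camera adjusted p = 1.21e-06; adjusted p = 0.405 with an estimated correlation). The chemokine genes Ccl5 (-1.87 ± 0.17), Ccl2 (-1.61 ± 0.08), Ccl8 (-1.18 ± 0.11, its Fra-1hep channel well above background on 4 of 5 arrays) and Ccl4 (-1.09 ± 0.07) fell. The 1 rise was in Cxcl1 (1.63 ± 0.34), chosen after its value was seen.

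Stellate cell, fibroblast and matrix genes fell with them: 22 of 34 were lower, 1 was higher and 11 did not pass (23 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 9.23e-10; adjusted p = 0.405 with an estimated correlation). The collagen gene Col1a2 (-1.62 ± 0.11), Timp1 (-1.44 ± 0.07), Dcn (-1.07 ± 0.09) and Vim (-0.94 ± 0.06) fell. Of 28 endothelial markers, 17 fell, 1 rose and 10 did not pass (20 and 2 adjusted over the list alone; camera adjusted p = 2.96e-05; adjusted p = 0.605 with an estimated correlation). Lyve1, a marker of sinusoidal and lymphatic endothelium, fell by 1.52 (SE 0.11), and the rise was in Flt1 (1.00 ± 0.13), chosen after its value was seen. Markers of T, NK and B cells had 12 of 26 lower, 0 higher and 14 not passing (13 lower adjusted over the list alone; median -0.23, camera adjusted p = 0.00223; adjusted p = 0.547 with an estimated correlation), with Cd3d (-0.39 ± 0.07) and Lck (-0.39 ± 0.07) as examples. With the control pool's spread, 15 matrix genes, 10 endothelial and 6 lymphocyte markers fell.

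Neutrophil markers moved the opposite way. Of 18 tested, 11 rose, 1 fell and 6 did not pass (12 and 4 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00313; adjusted p = 0.701 with an estimated correlation). The genes Mpo (2.74 ± 0.22), Camp (2.63 ± 0.30) and S100a8 (2.60 ± 0.29) rose, and Lcn2, which hepatocytes also express, fell by 1.80 (SE 0.10). With the control pool's spread, 7 rose and 1 fell; 3 fell without mouse 2 and 4 without the swapped array. The list's median was highest in mouse 2 at 1.12 and lowest in mouse 3 at 0.20. The pancreas exocrine list was called higher on 3 of 7 tested genes, with 0 falls and 4 not passing, as adjusted over the list alone (camera adjusted p = 0.009; adjusted p = 0.405 with an estimated correlation). Cela1 led it, followed by Amy2a5 (0.54 ± 0.07) and Ctrb1 (0.29 ± 0.06), while Ctrl at 0.10 did not pass. Amy2a5 lay at 0.25 without the swapped array, and its other probe, at 0.22, did not pass. The list's call ended without the swapped array (adjusted p = 0.145) and without a filter on dim probes (adjusted p = 0.179). Ctrb1 did not pass under median centring (0.23, adjusted p = 0.113) or with the control pool's spread added (adjusted p = 0.0582).

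**Figure D2:**
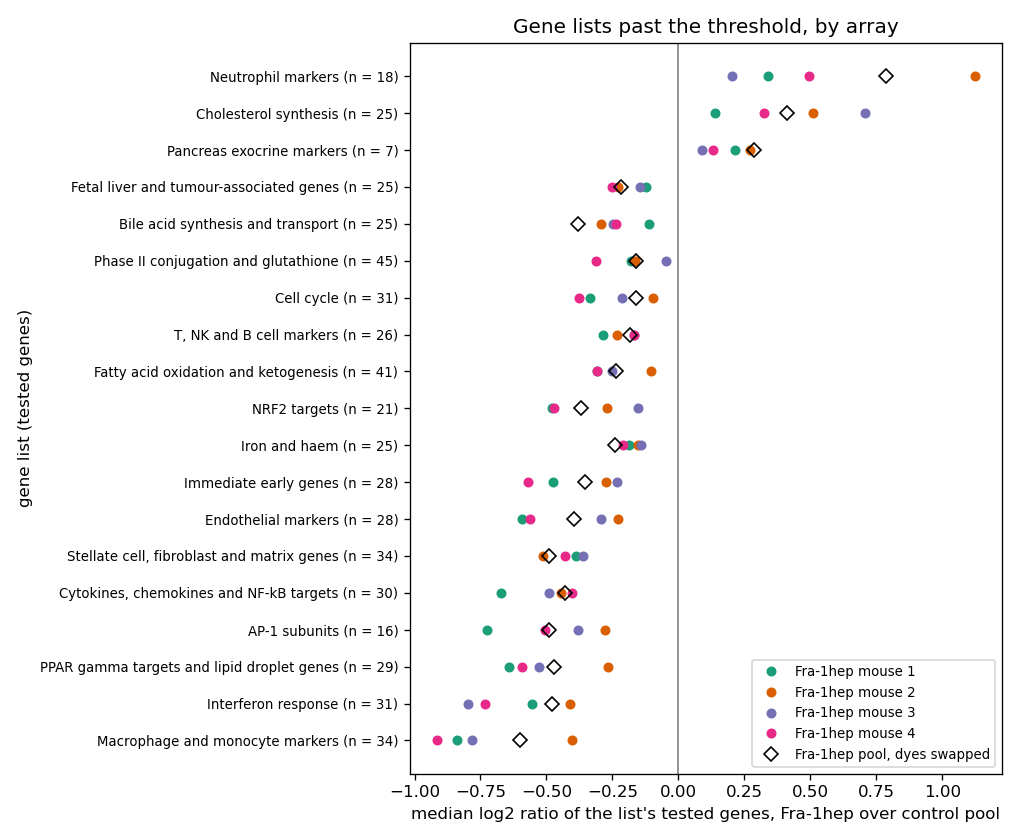
Median log2 ratio of Fra-1hep over the control pool on each array (horizontal axis) for the 19 lists that camera called (vertical axis, tested genes in parentheses); filled circles are the 4 mice and open diamonds the pool with swapped dyes. Macrophage marker medians lie between -0.92 and -0.40 and those of neutrophil markers between 0.20 and 1.12.

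Cell cycle genes had 13 of 31 members lower, 1 higher and 17 not passing, the same as adjusted over the list alone (median -0.22, camera adjusted p = 0.00291; adjusted p = 0.701 with an estimated correlation). With the control pool's spread, 7 fell and 0 rose. Ccnd1, which encodes a G1 cyclin (-1.05 ± 0.12), and the replication genes Mcm3 (-0.88 ± 0.09) and Mcm4 (-0.69 ± 0.08) fell. In the list of fetal liver and tumour-associated genes, 10 of 25 fell, 1 rose and 14 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.00214; adjusted p = 0.405 with an estimated correlation). Ly6d fell by 1.89 (SE 0.10) and S100a11 also fell (adjusted p = 4.42e-05), and the rise was that of Tff3.

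Acute phase genes split, and the list was not called (camera adjusted p = 0.122, and 0.039 without mouse 2). Of 30 tested, 7 rose, 12 fell and 11 did not pass (8 and 17 adjusted over the list alone). Orm3 (-2.67 ± 0.14), Saa3 (-2.06 ± 0.10) and Lcn2 (-1.80 ± 0.10) fell. The fibrinogen chain gene Fgb rose by 1.63 ± 0.06, with a dye effect of 1.00: its ratio averaged 2.64 in the 4 mice and was 0.63 in the swapped pool. The metallothionein genes Mt2 (2.36 ± 0.15) and Mt1 (1.83 ± 0.14), chosen after their values were seen, also rose.

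Phase I xenobiotic genes also split, with 11 of 54 higher, 14 lower and 29 not passing (11 and 15 adjusted over the list alone), and camera did not call them (adjusted p = 0.891). The cytochrome P450 genes Cyp2c55 (2.58 ± 0.06) and Cyp2c29 (1.09 ± 0.07) rose and the carboxylesterase gene Ces1e fell by 1.35 (SE 0.07). Cyp2c38 rose by 1.52 ± 0.08 at its brightest probe, while its other probe fell by 0.63. Among male-biased liver genes, 4 of 26 rose, 11 fell and 11 did not pass (6 and 12 adjusted over the list alone; camera adjusted p = 0.0945, but 0.0268 without mouse 4, 0.0354 with the swapped array turned and 0.019 without a filter on dim probes). Mup2 (-3.05 ± 0.18), Mup4 (-2.45 ± 0.15, and -0.47 at its other probe), Mup6 (-2.11 ± 0.14) and Mup3 (-1.95 ± 0.15) fell. Among female-biased genes, 3 of 20 rose, 10 fell and 7 did not pass, the same as adjusted over the list alone (camera adjusted p = 0.0743, but 0.0122 without mouse 3, 0.0414 with the swapped array turned, 0.0261 under median centring and 0.0264 without a filter on dim probes). Cyp3a16 (-2.76 ± 0.17) and Cyp3a41b (-2.27 ± 0.16) fell and Atp6v0d2 (2.28 ± 0.12, and 1.52 at its other probe) rose. With the control pool's spread, 2 female-biased genes rose and 6 fell.

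A dye effect, the part of the Cy5 over Cy3 ratio that did not turn with the swap, passed the threshold in 893 features, 763 higher in Cy5 and 130 in Cy3. Of these, 459 also had a genotype effect. The count was 459 without mouse 3, 414 without mouse 4, and 11570 with median centring in place of loess. These counts cannot tell dye apart from a deviation of the swapped array or of its Fra-1hep pool. No other array had its dyes swapped, and the test's spread comes from the single mice alone.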

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

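Of the tests in this part, the 3 on neutrophil genes were chosen after the result was seen. In 9 of 213 genes and lists, 1 of the 4 mice lay far from the other 3, measured as its gap to the nearest mouse over the whole range. Chance gives about 1 in 20 such cases, so 9 are no more than chance.

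For Mlxipl the ratio was 0.890, with mouse 4 at 0.93 and the others between 0.73 and 0.76. For Slco1a4 it was 0.917, with mouse 3 at -1.64 against -2.14 to -2.10. Lpl had 0.941, with mouse 2 at -0.14 against -0.58 to -0.55. Hk1 had 0.839, with mouse 2 at -0.30 against -0.67 to -0.61, and its other probe gave 0.07. Cyp2c55 had 0.843, with mouse 3 at 2.42 against 2.58 to 2.61. Fgb had 0.830, with mouse 4 at 2.51 against 2.66 to 2.69. For Itgax the ratio was 0.911, with mouse 2 at -0.95 against -1.48 to -1.44. Dcn had 0.931, with mouse 1 at -0.84 against -1.25 to -1.22. S100a8 had 0.840, with mouse 2 at 3.68 against 2.01 to 2.27.

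S100a8 belongs to the neutrophil marker list, of which 11 genes rose. Without mouse 2, 11 of the 11 genes that rose kept their call, S100a8 at 2.41 ± 0.07 among them. The standard error of S100a8 was 0.29 with mouse 2 included. Leaving out the farthest mouse shrank the spread, which made kept calls more likely. The fit without mouse 2 also keeps the swapped pool, which may hold RNA of mouse 2, so it may not leave that mouse out in full. The list's median also lay above 0 in mice 1, 3 and 4 (0.34, 0.20 and 0.49), so the rise did not rest on mouse 2 alone. With the control pool's spread added, 7 genes rose. More residual blood in the Fra-1hep livers would raise globin genes too, but the 4 tested globin genes had a median of -0.56 with 0 rises, and their median lay below 0 on each of the 5 arrays. More mature neutrophils would raise the receptor genes Csf3r, Cxcr2, Fpr1 and Fpr2 too, a rise that was not seen. Of these 4, 0 rose past the threshold and 0 fell. A gene that did not pass, or was too dim to be tested, is not shown to be unchanged, so this explanation stays open.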

How the results depend on the processing

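Of the 5717 features called, 1051 passed against a minimum change of 1.2-fold (332 higher, 719 lower) and 2846 with the control pool's spread added, a setting chosen after seeing the data (1085 higher, 1761 lower). Both raise the size of change needed by construction, and all 2846 and all 1051 were among the 5717. Without the swapped array and its dye term, 3641 features rose in place of 2402 (7718 in all), of which 41 were called the opposite way; dye effects then count as genotype by construction. Median centring in place of loess gave 1406 rises and 4337 features, with 32.4% of calls higher against 42.0%; the cause was not tested. It also gave 11570 dye effects in place of 893, for a cause also not tested.

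Leaving out each mouse in turn gave 4281 to 5488 features (1710 to 2315 higher, 2571 to 3268 lower), 18 to 22 lists and 414 to 719 dye effects. The slide as a block gave 5488, the same fit as without mouse 1. In every other setting the counts of features and lists stayed within 1.5 times, and lists called ran from 18 to 22. Of the genes that the naming rule takes, 166 passed the threshold. Among these and the called lists, 0 changed sign while called in any setting. Among all features called, 41 were called the opposite way without the swapped array and 1 with the mean of all probes. Of the 166, 147 kept their call with the control pool's spread, 119 against a minimum change, and at least 155 of those tested in every other setting.

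Without genes that other lists share, chosen after seeing the data, 17 of the 19 lists kept their call; conjugation genes (adjusted p = 0.163) and iron genes (0.34) did not, and periportal genes, with a median of 0.01 before, were called lower with a median of -0.68 (0.00189). No paired analysis was possible because the controls were 1 pool. For the same reason no other splits of the samples into groups could be counted. With the processed signals, log2 changes of dim genes were over 1.5 times those of the main fit. Gpnmb was at -4.21, Fos at -1.70, Sult1e1 at -2.84 and Ccl8 at -2.47, and the neutrophil median became 1.73. The offset of 50 in the main fit draws ratios of dim genes toward 0 by construction. Which of the 2 settings lies nearer the true changes was not tested. Probes near background limit what can be said of dim genes, Fosl1 first among them.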

Other observations

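The tests on non-hepatocyte markers and on Asns in this part, and those with the control pool's spread added, were chosen after the result was seen. Of the lists fixed in advance, those not yet described were not called by camera. Amino acid and urea genes went both ways, with 11 of 40 higher and 10 lower: the serine dehydratase-like gene Sdsl rose by 0.84 ± 0.07 and Gnmt by 0.72 ± 0.07, while the transporter Slc7a2 fell by 0.85 (SE 0.06). Of 24 periportal genes 7 rose and 8 fell, with Etnppl at -1.78 ± 0.10, and of 23 pericentral genes 5 rose and 6 fell, with Glul at -1.05 ± 0.12. Hepatocyte identity genes had 7 of 30 higher and 3 lower, with Ahsg at 0.71 ± 0.06; Ahsg had a dye effect of 0.58, with 1.29 without the swapped array and 0.13 in the swapped pool. Without that array 12 identity genes rose, 5 fell and the list was called (camera adjusted p = 0.0162), as under median centring (0.0498). Fatty acid synthesis had 6 of 28 higher and 4 lower, with Mlxipl at 0.56 ± 0.06, Insig2 at -1.56 ± 0.10 and Elovl3 at -1.74 ± 0.18. Glucose genes had 5 of 28 higher and 8 lower, with Hk2 at -1.17 ± 0.09, and lipoprotein genes 6 of 20 higher and 4 lower, with Apoc3 at 0.55 ± 0.06 (0.88 without the swapped array). In the growth hormone and IGF axis 5 of 17 fell and 0 rose, with Igfbp2 at -2.22 ± 0.13.

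Cholangiocyte and progenitor markers had 4 of 27 higher and 3 lower, led by Tff3, Anxa13 and St14 upward and Dmbt1 at -2.76 ± 0.10, its Fra-1hep channel well above background on 4 of 5 arrays; Krt19 (0.47), Sox9 (0.01) and Epcam (0.10), chosen after their values were seen, did not pass. The list's camera adjusted p was 0.102, and 0.0135 without mouse 2, when 10 rose, 0.0358 under median centring and 0.0474 with both channels above background on all arrays. Heat shock genes had 4 of 15 lower and 0 higher, led by Hspb1 at -1.53 ± 0.09 (camera adjusted p = 0.0619, and 0.0156 without mouse 4 and 0.0111 without a filter on dim probes). Red cell markers had 6 of 11 lower and 0 higher (camera adjusted p = 0.0743, but 0.0242 without mouse 2, 0.0446 with the swapped array turned, 0.0492 under median centring, 0.0218 without a filter on dim probes and 0.028 with both channels above background on all arrays); with the control pool's spread added 0 of the 11 fell, Hba-a1 at -0.66 ± 0.14 among them (adjusted p = 0.0546). Adipocyte markers had 3 of 11 higher and 5 lower, with Car3 at -2.31 ± 0.15. Retinoid genes had 4 of 20 higher and 5 lower, clock genes 3 of 19 higher and 2 lower, respiratory chain genes 2 of 48 higher and 5 lower, ER stress genes 1 of 27 higher and 2 lower, skeletal muscle markers 2 of 7 higher and 1 lower, and markers of kidney and other tissues 0 of 10 higher and 1 lower. Adjusted over the list alone, higher and lower counts became 7 and 4 for fatty acid synthesis, 7 and 5 for lipoproteins, 6 and 8 for glucose, 8 and 10 for periportal, 7 and 4 for hepatocyte identity, 6 and 5 for retinoid, 4 and 5 for adipocyte, 1 and 6 for red cell, 1 and 2 for respiratory chain and 1 and 1 for ER stress genes. For the other lists in this part they were the same. With the pool's spread, higher and lower counts became 3 and 1 for lipoproteins, 3 and 4 for glucose, 2 and 5 for pericentral, 4 and 8 for periportal, 4 and 2 for hepatocyte identity, 3 and 3 for retinoid, 3 and 0 for clock, 1 and 1 for respiratory chain, 1 and 1 for ER stress, 0 and 2 for heat shock and 0 and 0 for muscle genes. Without mouse 1, 11 fatty acid synthesis genes rose, and without mouse 2, 3 or 4, 3 glucose genes did. Without mouse 4, 3 pericentral genes rose, and 2 lipoprotein and 2 respiratory chain genes fell. Without the swapped array, 9 glucose and 5 ER stress genes rose, 3 growth hormone genes rose, and 7 respiratory chain genes rose and 10 fell. Median, mean and test differed in sign for fatty acid synthesis, phase I, periportal, growth hormone, retinoid, clock and adipocyte lists.

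The sex of the mice is not given in the sources used here. Mouse 3 had lower ratios than the other mice in male-biased genes, chosen after their values were seen. Cyp4a12a was at -1.69 against -0.23, -0.18 and 0.44, and Hsd3b5 at -2.54 against -0.63, -1.07 and -1.17. The Y-linked genes Ddx3y, Eif2s3y and Uty lay between -0.06 and 0.03 in mouse 3 and between 0.01 and 0.23 in the others. These ratios near 0 give no sign that mouse 3 differs in sex from the control pool. The median of the male-biased list was -0.96 in mouse 3 and between -0.43 and 0.01 in the other mice. That of the female-biased list was 0.19 in mouse 3 and between -1.11 and -0.29 in the others.

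Of 122 tested markers of macrophages, matrix-producing cells, endothelium and lymphocytes, 76 fell, with 12 of 26 for lymphocytes; the 4 lists had adjusted p from 0.405 to 0.605 with an estimated correlation. A larger hepatocyte share that dilutes every other cell type alike would lower neutrophil genes by as much. Their list median, however, lay above that of macrophages by 0.98 to 1.53 on the log2 scale on every array. Whether other cell types were exceptions too is less clear. Cholangiocyte and progenitor markers had a median of 0.16, but of -0.24 in mouse 2, and camera did not call the list (adjusted p = 0.102). The Kupffer cell markers Clec4f, Vsig4 and Timd4 did not pass, which does not show them unchanged. They were chosen after their values were seen, from a list in which 25 of 34 members fell. Dilution of part of the cells, beside a separate rise of neutrophils, stays open. Dye bias would turn the sign on the swapped array, where 4 of the 4 list medians stayed below 0. An unusual control pool cannot be told apart from an effect of genotype, since single control mice were not measured; with the pool's spread added, 51 of the 76 members that fell kept their call.

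Asns rose far more than any other named gene, which prompted a search for its source. A general amino acid response through the transcription factor ATF4 would raise its other targets, but 2 of 23 tested targets rose, Vldlr (0.99) and Shmt2 (0.47, and 0.31 without the swapped array), and 3 fell; the target list was written after Asns was seen. A change of the chromosome region would move its neighbours, but 0 of the 20 nearest tested genes changed at least 2-fold, the largest by 0.61 on the log2 scale; 7 of the 20 passed the threshold, beside 4129 of 13524 named genes. A probe artefact cannot be excluded, since 0 other Asns probes were kept. The source of the rise stays open.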
